A study of Arabidopsis thaliana with 9 samples.

How the data were processed

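Leaf RNA from Arabidopsis thaliana was profiled on 9 1-colour Agilent arrays, 1 per sample, with the 3 biological replicates per group that the series design gives. Per the labels' protocols, plants grew on MS medium with 1.5% sucrose under 12 h of light at 70 µmol per square metre per second and 12 h of dark at 22 °C. White and green sectors of var2-1 leaves were separated surgically at 4 weeks, per the series design. RNA was extracted with an RNeasy Plant kit and checked on a Bioanalyzer. From 500 ng of total RNA, cRNA was labelled with Cy3 by the Quick Amp kit, per the labels' protocols. Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.

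The deposited intensity of each spot is, per the file headers, the green-channel processed signal, for which the headers list background subtraction and spatial detrending. The submitters' combined value table held the same numbers spot by spot, with 0 spots differing on any array, so its scale is linear intensity with no centring and no log. Its column medians were 148, 174 and 191.5 in wild type, 118, 168 and 90.6 in white sectors, and 122, 194 and 124 in green sectors. All further steps were computed here from the processed signal.

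Control spots and spots marked as outliers by the scanner software were left out. Each array's log2 intensity was set against its 75th percentile over non-control probes, so every level and change is on a log2 scale. Spots of the same probe were averaged. Of 43603 probes, 38413 carried a locus code and 5190 did not. The 29030 loci were represented by the probe that was brightest on average over the 9 arrays. Names came from the TAIR10.1 gene table, used for names only, in which 28595 loci matched and 10499 had a symbol. A probe listing further loci was counted for its main locus, as was the case for 367 of the genes tested. Among 5473 genes with several tested probes, called probes went both ways in 5, 11 and 0 genes in the 3 comparisons.

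A gene was tested if it was well above background, by the scanner software's own mark, on all 3 arrays of at least 1 group, which left 18708 of 29028 genes with a value. All 9 arrays entered a single limma fit (lmFit and eBayes, two-sided, 6 residual degrees of freedom) with group as the only term. Adjusted p-values are those of limma after Benjamini-Hochberg adjustment over all genes tested, and a gene was called changed at adjusted p under 0.05. Changes are given as log2 of the group named before over the group named after. Where no probe of a gene was well above background on any array of a group, the change is given as "at least N-fold". That bound sets the bright group's mean against the mean, per array, of the higher of the dim probe's value and the lowest signal well above background. Where a group was well above background on only some of its arrays, a bound chosen after the values were seen raises the other arrays in the same way.

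Fixed lists of genes, 31 in number with 541 memberships, and all 66 plastid-encoded loci on the array formed the gene groups. Of these memberships 7 were left out because the name and the locus did not match, and 1 locus was not on the array. Groups with at least 5 tested members, 30 of them, were tested with camera (limma) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the groups of a comparison. The same test with a correlation estimated from the data and fry (limma) were run beside it, and counts of changed members are given over all genes and adjusted over the list alone. Trichome markers and markers of meristem and young leaf primordia had 2 tested members each and were not tested as groups. The fixed lists, their tests, the rule for named genes and the alternatives were chosen before the data were examined. The iron and MADS-box groups and the tests of the 3 patterns weighed were chosen after.

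Named genes follow a fixed rule. Each comparison names VAR2, FTSH8, VAR1, FTSH1, CSD1, CSD2, FSD1 and GLK1. It also names the 4 largest rises and the 4 largest falls among called genes with a symbol, no overlap between the 3 arrays of the groups, and signal well above background in the higher group. The fixed rule allowed a dim group there, and a second ranking with both groups measured was added to it. From each of the 10 groups with the largest share of called members each comparison names the 2 members with the largest change in the group's main direction. Up to 2 called members are named from the antioxidant, chaperone, jasmonate, protease and cell type groups. Further genes named in the text were chosen after their values were seen.

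Replicate numbers are shared between groups, so the correlation across genes of same-numbered arrays' deviations from their group means was examined before the blocked fits were compared. White and green sectors with the same number lay on the same slide, and their deviations correlated at 0.386, 0.490 and 0.347. Those numbers may therefore pair the sectors, but the labels do not state a pairing, and it cannot be told apart from the shared slide. Green replicate 2 and wild-type replicate 3, on the same slide with different numbers, correlated at 0.571. Same-numbered white sectors and wild type gave 0.384, 0.0926 and −0.105, and green sectors and wild type gave 0.631, −0.00725 and −0.273, so those numbers do not pair. Genes are not independent replicates, so no p-value is attached to these correlations.

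The fit was tested on simulated data with known changes placed among 18708 genes. For white against green sectors, 44.0% of 50 genes changed 2-fold and 86.0% of 50 changed 4-fold were recovered, with 2 unchanged genes called. For white sectors against wild type the shares were 48.0% and 92.0%, with 5 unchanged genes called. For green sectors against wild type they were 54.0% and 92.0%, with 6 unchanged genes called. The simulated noise was independent between arrays and equal in all groups, and few genes were changed. In the data 43.5% of genes were called in white against green sectors, and wild-type arrays agreed less well than the others. The simulated shares and false calls therefore describe the fit under that setting and not these comparisons. The tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.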

Results

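Transcript levels were measured on 9 arrays covering wild-type leaves (Columbia), white sectors and green sectors of the yellow variegated 2 mutant (var2-1), with 3 arrays per group. VAR2 encodes FtsH2, a subunit of the thylakoid FtsH protease that removes damaged photosystem II protein, and the mutant forms leaves with green and white sectors. Each array held 43803 non-control spots. The share of spots well above background was 63.3%, 66.9% and 70.2% in wild type, 61.9%, 66.3% and 58.4% in white sectors, and 61.8%, 68.4% and 62.6% in green sectors. No spot was saturated (0 on every array). The number of arrays limits the precision of every value. The arrays lay on 3 slides. Slide 1 held replicate 1 of each group, slide 2 held wild-type replicates 2 and 3 with white and green replicate 2, and slide 3 held white and green replicate 3.

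VAR2 (AT2G30950) separated the genotypes on every array. Its log2 level relative to the array's 75th percentile was 5.75, 6.09 and 5.75 in wild type, 3.34, 3.51 and 3.39 in white sectors, and 2.75, 3.03 and 2.65 in green sectors. Against wild type it fell 5.46-fold in white sectors (log2 −2.45, SE 0.145, adjusted p = 2.28e-05) and 8.29-fold in green sectors (−3.05, adjusted p = 1.55e-04). Between the sectors it was higher in white (log2 +0.60, adjusted p = 0.0103), a call that was lost when all probes of the gene were averaged. The related FtsH subunits FTSH8, VAR1 and FTSH1 passed the threshold in no comparison. Their log2 changes were −0.32, −0.17 and −0.34 for white against green, −0.28, +0.06 and −0.24 for white against wild type, and +0.05, +0.23 and +0.09 for green against wild type.

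**Figure D1:**
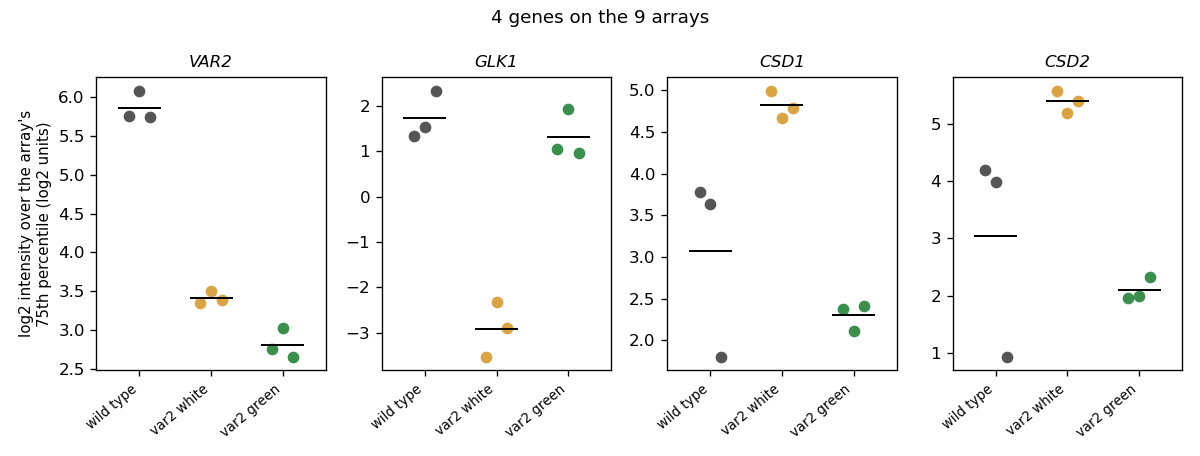
Log2 intensity over each array's 75th percentile (vertical axis, log2 units) of VAR2, GLK1, CSD1 and CSD2 by group, with a point per array in replicate order and a line at the mean of the 3 arrays. VAR2 lies at 5.75 to 6.09 in wild type and at 2.65 to 3.51 in var2 sectors, and CSD2 in wild-type replicate 3 lies at 0.93 against 4.19 and 3.98 in replicates 1 and 2.

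White sectors separated from all other arrays. The first principal component carried 68.6% of the variance and placed white sectors at +91.9 to +102, wild type at −69.4 to −28.1 and green sectors at −58.8 to −51.5. The second component carried 13.7% and ran from wild-type replicate 1 (+47.9) to wild-type replicate 3 (−58.0). Across genes, arrays of a group correlated at 0.945 to 0.982 in wild type, 0.988 to 0.992 in white sectors and 0.975 to 0.992 in green sectors. Wild-type replicate 3 stood apart, with 2258 genes at least 2-fold away from the mean of the other replicates of its group, against 1560 for wild-type replicate 1 and 683 for wild-type replicate 2 and 225 to 939 for the var2 arrays. Its CSD1 level was 1.80 against 3.78 and 3.63, its CSD2 level 0.93 against 4.19 and 3.98, and its CCA1 level −3.82 against 0.18 and −0.21. CCA1, a morning clock gene, is named here after its values were seen.

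**Figure D2:**
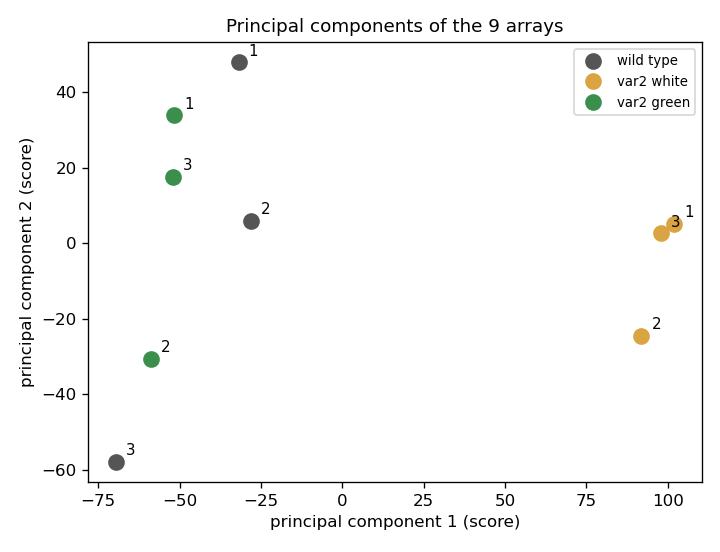
Scores of the 9 arrays on the first and second principal components (horizontal and vertical axes), coloured by group and numbered by replicate. White sectors lie at +91.9 to +102 on the first axis, and the 3 wild-type arrays spread from −58.0 to +47.9 on the second.

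White sectors were compared with green sectors of the same genotype to ask which transcripts differ with the state of the chloroplasts. White sectors carried less transcript for light harvesting, photosystems and carbon fixation, for cell division, for jasmonate and wound responses and for vascular and guard cells, and more for heat shock proteins and chaperones, for cytosolic ribosomes and for plastid transcription. These group calls were made at camera's preset correlation. With a correlation estimated from the data 0 of 30 groups passed. Under fry, which does not set a group against the other genes, 21 passed, these groups among them. The carbon fixation call was also lost under quantile scaling. The copper/zinc superoxide dismutase genes CSD1 and CSD2 were higher in white sectors. Of 18708 genes tested, 8136 changed, 3672 higher and 4464 lower in white, and 3769 of them changed at least 2-fold (1070 higher and 2699 lower). The balance of directions depended on the scaling, with 4014 higher and 4012 lower under quantile normalization and 4077 and 3924 with normexp background correction before it. The groups' arrays did not overlap in 8101 of the called genes, and over all genes 61.0% showed no overlap where 10% would by chance. In 554 called genes the dimmer group was not well above background on any array. With the slide as a block 9411 genes were called.

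The largest measured rises in white over green were in PI (log2 +7.35, 163-fold, adjusted p = 4.45e-06), a floral homeotic gene, and in NIT2 (+6.90), a nitrilase. GLYI7 (+6.90) and GLYI4 (+6.21), of the glyoxalase I family, followed. Each of these genes was not well above background on 1 of the 3 green arrays, and with that array set to the background limit the rises were at least 7.29, 6.63, 6.85 and 6.18. Where green sectors were not well above background, DIN2, a dark-inducible beta-glucosidase, rose at least 148-fold and NAS3, a nicotianamine synthase, at least 99.0-fold. The seed storage gene PAP85 rose at least 86.1-fold and the defence-related dehydrogenase gene ELI3-2 at least 70.9-fold. The largest measured falls were in the jasmonate-induced vegetative storage protein genes VSP2 (−8.13, adjusted p = 1.87e-06) and VSP1 (−7.99). The iron-deficiency regulators BHLH100 (adjusted p = 1.21e-04) and bHLH39, well above background on 1 of the 3 white arrays, fell at least 208-fold and 89.9-fold.

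Photosynthesis genes moved together. Of 35 nuclear-encoded photosystem and electron transport genes 30 fell and 1, PSB28 (+0.51), rose, and the counts were the same adjusted over the list alone. Their median was −0.81, the camera adjusted p = 4.86e-08, and the adjusted p = 0.482 with an estimated correlation. The energy-dissipation gene NPQ4 fell by 1.97 and the oxygen-evolving complex gene PSBQ-2 by 1.94. Light-harvesting genes fell in 16 of 21 cases (18 adjusted over the list alone), with a median of −0.97 (camera adjusted p = 6.56e-06, and adjusted p = 0.482 with an estimated correlation). LHCB2.3 (−5.50) and LHCB4.2 (−2.28) fell most. Calvin-Benson cycle genes fell in 12 of 20 cases (14 adjusted over the list alone), with a median of −0.51 (camera adjusted p = 4.80e-04, and adjusted p = 0.546 with an estimated correlation). That group's call was also lost under quantile scaling. GLK1, a transcription factor that drives photosynthesis genes, fell 18.8-fold (−4.23, SE 0.399, adjusted p = 1.29e-04). Within slides 1, 2 and 3 the medians were −0.87, −0.79 and −0.71 for photosystem genes, −0.98, −0.82 and −0.96 for light-harvesting genes and −0.54, −0.53 and −0.47 for the Calvin-Benson cycle.

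Cell cycle genes and jasmonate and wound genes fell too. Cell cycle and DNA replication genes fell in 19 of 21 cases (20 adjusted over the list alone), with a median of −1.83 (camera adjusted p = 1.28e-07, and adjusted p = 0.388 with an estimated correlation). The mitotic genes CDC20.1 and CYCB1;2, well above background on 1 and 0 of the 3 white arrays, were at least 7.31-fold and 6.88-fold lower. Jasmonate and wound genes fell in 16 of 20 cases (17 adjusted over the list alone), with a median of −2.12 (camera adjusted p = 1.87e-07, and adjusted p = 0.207 with an estimated correlation). Within slides 1, 2 and 3 the medians were −1.55, −1.82 and −2.04 for cell cycle genes and −1.95, −1.50 and −2.30 for jasmonate genes.

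Markers of several cell types fell in white sectors beside the groups above. All 10 xylem markers fell, with a median of −2.49 (camera adjusted p = 1.39e-06, and adjusted p = 0.314 with an estimated correlation). The secondary-wall cellulose synthase gene IRX1 fell by 2.90 and the xylan gene IRX9 was at least 3.21-fold lower. All 7 phloem markers fell, with a median of −1.20 (camera adjusted p = 1.36e-04, and adjusted p = 0.207 with an estimated correlation), led by SEOR1 (−2.13) and the sucrose transporter gene SUC2 (−1.70). Guard and myrosin cell markers fell in 8 of 9 cases, with a median of −1.18 (camera adjusted p = 4.83e-04, and adjusted p = 0.482 with an estimated correlation), with TGG2 at −7.03 and KAT2, well above background on 1 of the 3 white arrays, at least 5.75-fold lower. Epidermis and cuticle markers fell in 6 of 9 cases (8 adjusted over the list alone), with a median of −0.66 (camera adjusted p = 0.00485, and adjusted p = 0.41 with an estimated correlation), led by CER1 (−1.62) and ATML1 (−1.35). For xylem, phloem and guard cells the counts adjusted over the list alone were also 10, 7 and 8. Within slides 1, 2 and 3 the medians were −2.77, −2.18 and −2.43 for xylem, −1.36, −1.08 and −1.35 for phloem, −1.10, −1.18 and −1.26 for guard cells, and −0.66, −0.80 and −0.63 for epidermis.

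Chaperone, ribosome and plastid expression genes rose. Heat shock proteins and chaperones rose in 16 of 23 cases, also 16 adjusted over the list alone, with a median of +1.07 (camera adjusted p = 1.97e-06, and adjusted p = 0.207 with an estimated correlation). The mitochondrial small heat shock protein gene HSP23.6-MITO rose at least 36.7-fold and HSP17.6C (AT1G53540), well above background on 1 of the 3 green arrays, at least 60.8-fold. Both lay lower on white replicate 3 (−2.34 and −1.48) than on white replicates 1 (0.27 and 0.77) and 2 (0.43 and 1.46). Cytosolic ribosomal protein genes rose in 15 of 18 cases (all 18 adjusted over the list alone), with a median of +0.78 (camera adjusted p = 1.87e-07, and adjusted p = 0.207 with an estimated correlation), led by P40 (+1.09) and RPL10C (+1.06). Plastid transcription genes rose in 14 of 23 cases and fell in 2, PTAC16 (−1.47) and SIG4 (−0.59), both outside the naming rule. The counts adjusted over the list alone were the same, and the median was +0.64 (camera adjusted p = 4.80e-04, and adjusted p = 0.41 with an estimated correlation). FLN2 (+1.53) and FLN1 (+1.33), fructokinase-like partners of the plastid polymerase, rose most. Within slides 1, 2 and 3 the medians were +1.32, +0.94 and +0.91 for chaperones, +0.93, +0.74 and +0.69 for ribosomal proteins and +0.79, +0.47 and +0.73 for plastid transcription.

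Smaller shifts concerned plastid proteases and plastid ribosomes. FtsH, Deg, Clp and related proteases rose in 8 of 27 cases and fell in 2, DEG1 (−0.76) and DEG5 (−0.33), which were named after their values were seen. Adjusted over the list alone 7 rose and 1 fell, and the median was +0.24 (camera adjusted p = 0.0304, and adjusted p = 0.637 with an estimated correlation). FTSH12 (+1.08) and the Clp chaperone gene CLPC2 (+1.03) rose most. Plastid ribosomal protein genes rose in 6 of 33 cases (3 adjusted over the list alone), with a median of +0.16 (camera adjusted p = 0.0304, and adjusted p = 0.729 with an estimated correlation). Both groups lost their call with the slide as a random block. Within slides 1, 2 and 3 the medians were +0.24, +0.17 and +0.31 for proteases and +0.14, +0.12 and +0.21 for plastid ribosomal proteins.

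Antioxidant genes did not shift as a group but held some large single changes. Of 29 such genes 8 rose (9 adjusted over the list alone) and 5 fell, with a median of −0.03, a mean of +0.43 and an upward camera direction (adjusted p = 0.435). CSD2, the chloroplast copper/zinc superoxide dismutase gene, rose by 3.29 (9.80-fold, SE 0.742, adjusted p = 0.00763). Its cytosolic relative CSD1 rose by 2.52 (5.74-fold, adjusted p = 0.00281) and their copper chaperone gene CCS by 2.89 (adjusted p = 0.00226). These genes also varied widely within wild type, from 0.93 to 4.19 for CSD2, 1.80 to 3.78 for CSD1 and 0.99 to 3.30 for CCS. The iron superoxide dismutase gene FSD1 was not called (+0.03, adjusted p = 0.95). Copper homeostasis genes, which include CSD1, CSD2, CCS and FSD1, had 3 rises and 3 falls among 15, with a median of −0.14 and a mean of +0.15 (camera adjusted p = 0.831).

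The remaining groups did not pass the group test between the sectors. Senescence genes came closest, with 7 of 13 higher and 1 lower and a median of +0.67 (camera adjusted p = 0.0506). Chlorophyll and haem biosynthesis genes had 2 higher and 7 lower of 27 (median −0.21), and chloroplast development regulators 6 higher and 5 lower of 20 (median +0.29). Sugar and starch genes had 2 higher and 7 lower of 15 (median −0.46), and salicylate and pathogen defence genes 2 higher and 5 lower of 11 (median −1.25). Reactive-oxygen-responsive genes had 3 higher and 3 lower of 12 (median −0.74), and flavonoid genes 3 higher and 3 lower of 10, with a median of +0.13 and a mean of −0.26. Mitochondrial alternative respiration genes had 3 higher and 1 lower of 9 (median +0.28), and photorespiration genes 0 higher and 4 lower of 10 (median −0.30). Nitrogen assimilation genes had 1 higher and 3 lower of 10, and carotenoid genes 1 each way of 13. DNA damage genes had 1 each way of 8, and clock genes had 0 changes among 12 (0 adjusted over the list alone). The 66 plastid-encoded genes had 10 higher and 11 lower, with a median of +0.02 (camera adjusted p = 0.941). Mean and median also differed in sign for carotenoid, clock and plastid-encoded genes, each within 0.09 of 0 on the median, and camera pointed down for nitrogen and clock genes against a positive median. Adjusted over the list alone, senescence genes had 2 lower, chloroplast development regulators 8 higher, carotenoid genes 0 higher, and plastid-encoded genes 8 higher and 5 lower, and the other counts of this paragraph were the same.

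White sectors were next compared with wild-type leaves, which differ in both genotype and colour and, since the sectors were cut out, possibly in handling. Of the groups that passed the group test against green sectors, all but plastid proteases and plastid ribosomal proteins passed here in the same direction, and plastid-encoded transcripts passed as well. With a correlation estimated from the data 0 of 30 groups passed. In this comparison 7832 genes changed, 3553 higher and 4279 lower, and 3623 changed at least 2-fold (1123 higher and 2500 lower). The balance of directions again depended on the scaling, with 3804 higher and 3752 lower under quantile normalization and 3855 and 3584 with normexp background correction before it. The groups' arrays did not overlap in 7748 of the called genes, and over all genes 52.7% showed no overlap where 10% would by chance. With the slide as a block 8260 genes were called. In 521 called genes the dimmer group was not well above background on any array.

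The largest measured rises over wild type were in TPX2 (AT1G65970, log2 +7.82, SE 1.15, adjusted p = 0.0011), a thioredoxin-dependent peroxidase gene, and in GLYI4 (+5.51, adjusted p = 0.0187) and PI (+5.42). GLYI4 lay at −2.45, −2.22 and −8.41 in wild type. Its rise was 3.49 without wild-type replicate 3, and its call was lost without white replicate 1 or 2. The cell wall extensin gene EXT4 also rose (adjusted p = 7.62e-05), by at least 67.8-fold, since the probe that stands for it was well above background on 0 of the 3 wild-type arrays. TPX2 and GLYI4 were not well above background on wild-type replicate 3, and with that array set to the background limit their rises were at least 7.35 and 4.85. Without that array the TPX2 rise was 6.92. DIN2 rose at least 203-fold and NAS3 at least 126-fold over wild type, which was not well above background for either gene. The largest measured falls were again in VSP2 (−7.36) and VSP1 (−7.30), and BHLH100 and bHLH39 were at least 154.5-fold and 43.7-fold lower. GLK1 fell 25.0-fold (−4.64, adjusted p = 9.28e-05).

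Photosynthesis genes fell against wild type as well. Photosystem and electron transport genes fell in 24 of 35 cases and PSB28 (+0.55) rose (26 lower and 1 higher adjusted over the list alone). Their median was −0.59 (camera adjusted p = 3.10e-06, and adjusted p = 0.564 with an estimated correlation), with NPQ4 at −1.84 and PSBQ-2 at −1.66. Light-harvesting genes fell in 12 of 21 cases, also 12 adjusted over the list alone, with a median of −0.68 (camera adjusted p = 8.88e-04, and adjusted p = 0.568 with an estimated correlation). Calvin-Benson cycle genes fell in 9 of 20 cases, also 9 adjusted over the list alone, with a median of −0.34 (camera adjusted p = 0.00542, and adjusted p = 0.614 with an estimated correlation). Within slides 1 and 2 the medians were −0.61 and −0.75 for photosystem genes, −0.49 and −0.80 for light-harvesting genes, and −0.21 and −0.52 for the Calvin-Benson cycle.

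Cell cycle genes fell in 20 of 21 cases, also 20 adjusted over the list alone, with a median of −2.21 (camera adjusted p = 2.73e-08, and adjusted p = 0.317 with an estimated correlation). CDC20.1 was at least 5.76-fold lower and CYCB1;2 at least 5.18-fold. Jasmonate and wound genes fell in 16 of 20 cases (18 adjusted over the list alone), with a median of −2.19 (camera adjusted p = 3.78e-08, and adjusted p = 0.27 with an estimated correlation). Xylem markers fell in all 10 cases (median −2.29, camera adjusted p = 2.51e-06, and adjusted p = 0.317 with an estimated correlation), with IRX9 at least 4.14-fold lower and IRX1 at −2.86. Guard and myrosin cell markers fell in 8 of 9 cases (median −1.40, camera adjusted p = 6.03e-04, and adjusted p = 0.452 with an estimated correlation), with TGG2 at −6.37 and KAT2 at least 4.88-fold lower. Epidermis and cuticle markers fell in 6 of 9 cases (9 adjusted over the list alone, median −0.57, camera adjusted p = 0.0021, and adjusted p = 0.319 with an estimated correlation), with CER1 at −2.12 and ATML1 at −1.25. Phloem markers fell in 5 of 7 cases (median −0.77, camera adjusted p = 0.0081, and adjusted p = 0.317 with an estimated correlation), with SEOR1 at −1.39 and SUC2 at −1.17. For xylem, guard cells and phloem the counts adjusted over the list alone were the same. Within slides 1 and 2 the medians were −1.98 and −1.78 for the cell cycle, −2.76 and −2.08 for jasmonate, −2.20 and −2.24 for xylem, −0.70 and −1.49 for guard cells, −0.52 and −0.63 for epidermis, and −0.64 and −0.74 for phloem.

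Plastid-encoded transcripts rose in white sectors over wild type in 30 of 66 cases and fell in 2, with the same counts adjusted over the list alone. Their median was +0.45 (camera adjusted p = 6.90e-06, and adjusted p = 0.549 with an estimated correlation), with +0.88 on slide 1 and +0.31 on slide 2. Heat shock proteins and chaperones rose in 15 of 23 cases (16 adjusted over the list alone), with a median of +1.11 (camera adjusted p = 3.30e-06, and adjusted p = 0.3 with an estimated correlation). HSP23.6-MITO rose at least 50.4-fold and HSP17.6A at least 13.3-fold. The first of these lay at −2.34 on white replicate 3, below 0.27 and 0.43 on white replicates 1 and 2, so its size depended on the replicate. Cytosolic ribosomal protein genes rose in 13 of 18 cases (16 adjusted over the list alone), with a median of +0.58 (camera adjusted p = 8.27e-06, and adjusted p = 0.317 with an estimated correlation), led by P40 (+1.03) and AT3G09200 (+0.93). Plastid transcription genes rose in 15 of 23 cases and fell in 2, again PTAC16 (−1.13) and SIG4 (−0.63), with the same counts adjusted over the list alone. Their median was +0.54 (camera adjusted p = 1.70e-04, and adjusted p = 0.317 with an estimated correlation). FLN2 rose by 1.73 and the sigma factor gene SIG5 by 2.17 (adjusted p = 0.0418). The SIG5 rise was 1.24 without wild-type replicate 3, and its call was lost with the slide as a block. Within slides 1 and 2 the medians were +1.21 and +0.97 for chaperones, +0.56 and +0.57 for ribosomal proteins, and +0.60 and +0.61 for plastid transcription.

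Among antioxidant genes 9 of 29 rose and 4 fell against wild type, with a median of +0.17 (camera adjusted p = 0.166). The stromal ascorbate peroxidase gene SAPX rose by 2.61 and the glutathione peroxidase gene GPX7 by 2.54 (1.82 without wild-type replicate 3). CSD1 rose by 1.75 (adjusted p = 0.0158) and CSD2 by 2.35 (SE 0.742, adjusted p = 0.0332), while FSD1 was not called (+0.24, adjusted p = 0.572) except with array weights and without wild-type replicate 3 (+0.64, adjusted p = 0.0256). The CSD2 call was lost with the slide as a block and without any single white replicate, and the CSD1 call was lost without white replicate 1. Without wild-type replicate 3 the CSD2 rise was 1.303 and the CSD1 rise 1.115. White sectors held CSD2 at 5.58, 5.18 and 5.40, against 4.19, 3.98 and 0.93 in wild type.

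Other groups did not pass the group test against wild type. Chloroplast development regulators had 11 higher and 3 lower of 20, with a median of +0.39 (camera adjusted p = 0.0581). The light-signalling factor gene HY5 rose by 1.70 and the GATA factor gene CGA1 by 1.61 (adjusted p = 0.0436), the latter lost with the slide as a block and at 0.88 without wild-type replicate 3. Plastid proteases had 7 higher and 2 lower of 27 (median +0.28), with CLPC2 at +1.19, FTSH12 at +1.00 and VAR2 and DEG5 (−0.54) lower. Plastid ribosomal proteins had 6 higher of 33 (0 adjusted over the list alone, median +0.16). Senescence genes had 5 higher and 1 lower of 13, and mitochondrial alternative respiration genes 4 higher and 1 lower of 9 with a median of +1.43 (camera adjusted p = 0.112). Flavonoid genes had 4 higher and 3 lower of 10, with a median of +0.35 and a mean of −0.04, and F3H (+3.03) and TT7 (+1.03) rose. Chlorophyll and haem genes had 5 higher and 7 lower of 27, sugar genes 2 higher and 5 lower of 15, and photorespiration genes 0 higher and 5 lower of 10. Reactive-oxygen-responsive genes had 3 higher and 4 lower of 12, with a median of −0.42 and a mean of +0.28. Salicylate and defence genes had 2 higher and 3 lower of 11, with a median of −0.48 and a mean of +0.21. Copper genes had 3 each way of 15, nitrogen genes 1 higher and 3 lower of 10, and DNA damage genes 2 each way of 8. Carotenoid genes had 1 each way of 13, and of 12 clock genes LUX (−0.45), named after its value was seen, fell. Camera pointed down for copper, sugar and nitrogen genes against positive medians, and up for reactive-oxygen-responsive and defence genes against negative ones. Adjusted over the list alone, chloroplast development regulators had 12 higher, proteases 6 higher and carotenoid genes 0 higher, and the other counts of this paragraph were the same.

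Green sectors were compared with wild-type leaves to ask what the mutation changes in green tissue. The sectors had been separated surgically, and no cutting of wild-type leaves is stated above. Any effect of that handling cannot be told apart from genotype. Few genes passed the threshold beside VAR2 itself, and none of the 30 gene groups tested had more than 1 called member. No group covered the mitochondrial genome, where 11 of 54 transcripts were called higher. Of 64 nuclear loci in a region that copies mitochondrial DNA, 13 were called higher. Over all genes 0.66% were called. Both of these sets were chosen after the values were seen. In this comparison 124 genes changed, 85 higher and 39 lower, and 90 changed at least 2-fold (57 higher and 33 lower). At unadjusted p under 0.05 limma gave 2080 genes. The groups' arrays did not overlap in any of the 124 genes, and over all genes 15.2% showed no overlap where 10% would by chance. In 11 called genes the dimmer group was not well above background on any array. The count depended on single arrays. It was 729 without wild-type replicate 3 (480 higher and 249 lower), 73 and 45 without wild-type replicates 1 and 2, and 26, 44 and 21 without green replicates 1, 2 and 3. It was 64, 79 and 79 without white replicates 1, 2 and 3, which enter the shared spread. With the slide as a block 55 genes were called.

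Among the named genes the largest rise in green sectors was in MRD1 (log2 +4.87, 29.2-fold, SE 0.233, adjusted p = 1.55e-04), a gene first described by its response in a methionine-overaccumulating mutant. The amino acid permease gene AAP2 rose 6.05-fold (adjusted p = 5.23e-04), the phosphoglucan water dikinase gene PWD by 1.77 (adjusted p = 0.00954) and the floral gene SEP3 by 1.76 (adjusted p = 0.046). IAA34, an auxin response gene, rose at least 4.41-fold. ChlAKR, a chloroplast aldo-keto reductase gene, fell by 3.08 (adjusted p = 0.00845), SPL5, a phase-change factor gene with 1 of its 3 green arrays near background, by at least 2.87 (adjusted p = 0.0176) and the beta-glucosidase gene BGLU11 by 2.40 (adjusted p = 0.00845). The ubiquitin-fold gene MUB5 was at least 3.05-fold lower and the retroposon SADHU3-2 at least 2.38-fold lower. VAR2, MRD1, AAP2 and MUB5 kept their calls under every setting in which they were tested. MUB5, well above background on 0 of the 3 green arrays, was not tested where all 9 arrays had to be above background. The other called genes of this paragraph lost their calls under at least 2 settings. CSD1 (−0.77, adjusted p = 0.594), CSD2 (−0.94, adjusted p = 0.712), FSD1 (+0.21, adjusted p = 0.874) and GLK1 (−0.41, adjusted p = 0.776) were not called. Without wild-type replicate 3 CSD1 (−1.41, adjusted p = 0.00471) and CSD2 (−1.99, adjusted p = 0.00208) passed the threshold, and with array weights CSD1, CSD2 and FSD1 did.

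Plastid-encoded transcripts had the smallest camera adjusted p of the groups in green sectors. Their median was +0.56 (camera adjusted p = 2.99e-24, and adjusted p = 0.342 with an estimated correlation). A single locus, ATCG01230 (+0.86, adjusted p = 0.0208), passed the threshold over all genes, against 38 of 66 adjusted over the list alone, and its probe also lists ATCG00905. Phloem markers had a median of +0.53 (camera adjusted p = 5.67e-07, and adjusted p = 0.242 with an estimated correlation), with SWEET11 (+0.86, adjusted p = 0.0335) called over all genes and 6 of 7 markers adjusted over the list alone. Phloem markers were the only group past fry's test (adjusted p = 0.00931). Within slides 1 and 2 the medians were +0.84 and +0.45 for plastid-encoded genes and +0.79 and +0.41 for phloem markers. ATCG01230 and SWEET11 lost their calls with the slide as a block.

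A further 6 groups passed camera with 0 called members over all genes. Light-harvesting genes had a median of +0.28 (camera adjusted p = 6.36e-06, and adjusted p = 0.645 with an estimated correlation) and photosystem genes +0.21 (camera adjusted p = 9.75e-05, and adjusted p = 0.874 with an estimated correlation). Both were lost under quantile scaling. Cytosolic ribosomal protein genes had a median of −0.15 (camera adjusted p = 8.94e-04, and adjusted p = 0.58 with an estimated correlation) with 2 lower adjusted over the list alone. Sugar and starch genes had a median of +0.30 (camera adjusted p = 0.00348, and adjusted p = 0.322 with an estimated correlation), and that call was lost without wild-type replicate 3. Salicylate and defence genes had a median of +1.12 (camera adjusted p = 0.0075, and adjusted p = 0.58 with an estimated correlation) with 2 higher adjusted over the list alone. This call too was lost without wild-type replicate 3. Chlorophyll and haem genes had a median of +0.14 (camera adjusted p = 0.0334, and adjusted p = 0.737 with an estimated correlation), lost with the slide as a block. Adjusted over the list alone, light-harvesting, photosystem, sugar and chlorophyll groups had 0 called members. Within slides 1 and 2 the medians were +0.35 and +0.14 for light harvesting, +0.25 and +0.03 for photosystems, −0.32 and −0.13 for ribosomal proteins, +0.38 and +0.19 for sugar, +0.65 and +0.35 for defence, and +0.02 and +0.16 for chlorophyll genes.

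Xylem markers (median +0.12), guard cell markers (+0.21), epidermis markers (+0.01), cell cycle genes (−0.03), jasmonate genes (−0.20) and chaperones (−0.03) had 0 called members in green sectors against wild type. So had Calvin-Benson cycle genes (+0.15, camera adjusted p = 0.0963), clock genes (+0.39, camera adjusted p = 0.0963), chloroplast development regulators (+0.14), plastid transcription genes (+0.07), plastid ribosomal protein genes (−0.02), photorespiration genes (−0.02) and carotenoid genes (+0.03). Antioxidant (+0.11), copper (+0.03), reactive-oxygen-responsive (+0.37), flavonoid (+0.18), nitrogen (+0.02) and DNA damage genes (+0.12) also had 0. Adjusted over the list alone 1 nitrogen gene was lower and 1 DNA damage gene higher, and none of the groups of this paragraph passed camera. Elsewhere the alternative NADH dehydrogenase gene NDB2 (+0.91, adjusted p = 0.044) and the sugar transporter and senescence gene SWEET15 (+1.71, adjusted p = 0.0342) rose. NDB2 lost its call with the slide as a block and SWEET15 without any single green replicate. Plastid proteases had VAR2 as their only called member and a median of +0.00 with a mean of −0.08. Mean and median also differed in sign for mitochondrial alternative respiration, copper, nitrogen and epidermis groups, and camera took the sign of the mean for all of these except copper.

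**Figure D3:**
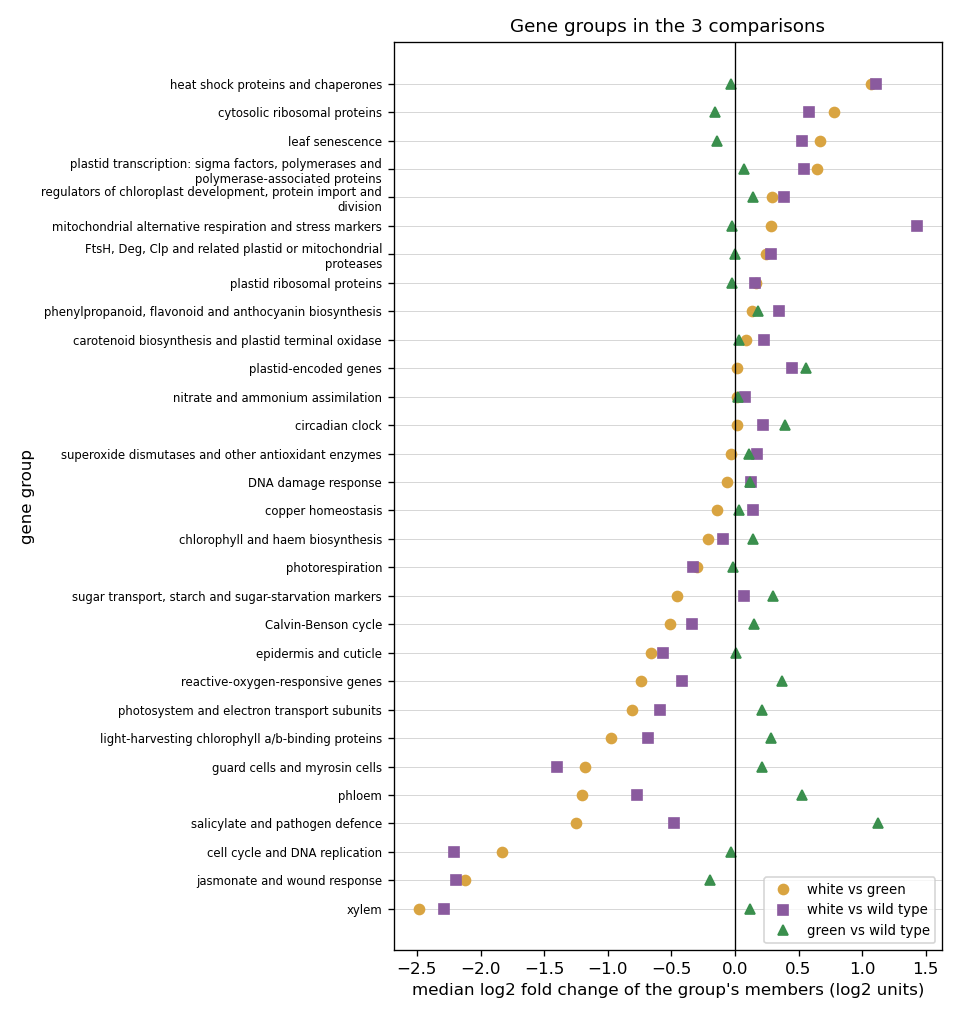
Median log2 fold change of each gene group (horizontal axis, log2 units) in white against green sectors (circles), white sectors against wild type (squares) and green sectors against wild type (triangles), ordered by the first. Xylem markers lie at −2.49 and −2.29 in the comparisons of white sectors and at +0.12 in green sectors against wild type, while plastid-encoded genes lie at +0.02, +0.45 and +0.56.

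Calls of white against green sectors and of white sectors against wild type overlapped in 6550 genes in the same direction, 2886 higher and 3664 lower, with 10 in opposite directions. These were 80.5% and 83.6% of the calls of the 2 comparisons. Independent lists of the same sizes would share 697 higher and 1021 lower genes, and 100 simulations of unchanged groups with the shared white arrays gave 0. Where no gene changes almost none is called, so this simulated overlap and those below were bound to lie near 0. They cannot tell how much overlap the shared arrays produce among real calls. The simulated arrays were also independent of each other, without the likeness seen between arrays of a slide. Across genes, which are not independent replicates, the fold changes correlated at 0.93 against 0.50 simulated, with a covariance of 1.08 against 0.0390. Changes of white sectors and of green sectors against wild type overlapped in 72 genes, 55 higher and 17 lower, with 28 in opposite directions. Independent lists would share 16.1 higher and 8.92 lower. The simulations gave a mean of 0.01 and at most 1, again because unchanged groups yield almost no calls. The correlation across genes was 0.0272 against 0.501 simulated, and the covariance 0.0117 against 0.0392. Changes of white against green sectors and of green sectors against wild type met in 27 genes in the same direction, 22 higher and 5 lower, and in 62 in opposite directions. There independent lists would share 16.7 higher and 9.31 lower, and the simulations gave 0 in the same direction. The correlation across genes was −0.34 against −0.50 simulated, and the covariance −0.156 against −0.0390. The 3 arrays of a shared group cannot be split into parts of 2, so part of the first 2 overlaps may come from the shared arrays. In the last pair the green arrays enter with opposite signs. Their shared noise therefore favours opposite directions and may add to the 62 genes there. No expectation for independent lists was computed for opposite directions. Not every value was in excess. The last pair shared 5 lower genes against 9.31 for independent lists, which the opposite signs of the green arrays may explain. The changes of both sectors against wild type correlated below their simulated value.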

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

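Probes that carry no locus code entered no comparison of genes, and a signal appeared in them. Of 5190 such probes 2024 were well above background in at least 1 group and were tested with the same limma fit. Between white sectors and wild type 440 of them passed the threshold, 173 higher and 267 lower in white, and 703 had an unadjusted p under 0.05. White against green sectors gave 480 (203 higher and 277 lower). Green sectors against wild type gave 0, with 147 at unadjusted p under 0.05. These probes cannot be tied to a gene by the array's own table, so they were left as counts.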

How the results depend on the processing

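The white sector counts moved most at the stricter thresholds, and the green sector count moved under more settings. White against green sectors gave 8136 genes, 5176 at adjusted p under 0.01 and 3769 at a 2-fold change or more, 11519 with array weights, and 6234 (without white replicate 1) to 9290 (without wild-type replicate 3) with an array left out. White sectors against wild type gave 7832, 4839 and 3623, 9512 with array weights, and 5928 to 7690 with an array left out. Green sectors against wild type gave 124 genes, 52 with no filter on dim probes, 55 with the slide as a block, 243 with the slide as a random block, 22 with only the groups compared in the fit, 2592 with array weights, 22 at adjusted p under 0.01, and 21 (without green replicate 3) to 729 (without wild-type replicate 3) with an array left out. The stricter thresholds lower counts by construction, and otherwise the cause was not tested.

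The overlap of white against green with white against wild type was 6550 genes, 3999 at adjusted p under 0.01 and 4909 to 6605 with an array left out. That of white and green sectors against wild type was 72, 32 with no filter, 33 with the slide as a block, 14 at adjusted p under 0.01 and 14 to 225 with an array left out. The cause was not tested.

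Gene groups past camera numbered 14, 13 and 8 in the 3 comparisons and 0, 0 and 0 with an estimated correlation. Under fry there were 21, 21 and 1. With an array left out they numbered 12 to 15, 13 to 16 and 5 to 10. A reversal occurred once: the median change of plastid and mitochondrial proteases in green sectors against wild type moved from +0.00 to −0.0749 (adjusted p = 0.0465) without wild-type replicate 3, and ran from that value to +0.0855 (without wild-type replicate 2) with an array left out. The cause was not tested. Of the other group medians 2086 kept their side of the threshold or, within slides, their size, 67 moved in size within slides, 80 lost and 46 gained a call. Of the named genes' values 2129 kept their side of the threshold, 115 lost and 11 gained a call. Apart from the medians within slides, sizes were not compared. CSD2 in white sectors against wild type, for example, kept its call without wild-type replicate 3 while its rise went from 2.353 to 1.303.

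With the replicate number as a block the counts were 9054, 8785 and 113, of which 7968, 7665 and 83 were called without the block. In green sectors against wild type, where the numbers do not pair, SEP3, SADHU3-2 and NDB2 and the chlorophyll and haem group fell outside the threshold and the Calvin-Benson cycle came inside. The replicate block changed no other call of a named gene or group. Genes near background are the least certain, since 18708 of 29028 genes with a value were bright enough to test.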

Other observations

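Iron-deficiency genes also fell in white sectors. These genes were grouped after their values were seen. Of 16 tested genes of the iron-deficiency response, all 16 were lower in white than in green sectors, with a median log2 change of −3.85, and 15 were lower than in wild type, with a median of −3.14. Several of them lay near background in white sectors, which makes the medians approximate. Besides BHLH100 and bHLH39, BHLH38 (at least 140-fold) and BHLH101 (log2 −6.71) fell against green sectors. The peptide genes IMA1 (−6.03), IMA2 (−5.94) and IMA3 (−5.37), which signal iron deficiency, fell with them, as did the iron-sensing ligase gene BTS (−2.20), the factor gene PYE (−2.28) and the transporter gene OPT3 (−2.55). The ferritin genes FER1 (+4.16), FER4 (+3.37), FER2 (at least 3.09-fold) and FER3 (+1.17), which store iron in plastids, rose against green sectors. Against wild type FER1 (+3.51), FER4 (+3.42) and FER2 (at least 3.72-fold) rose, and FER3 was not called (+0.96, limma adjusted p = 0.0757). VTL1, grouped with the ferritins after the values were seen, was called against neither green sectors nor wild type (limma adjusted p = 0.0985 and 0.158). In green sectors against wild type 0 of the 16 genes changed.

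Some flower-identity genes also moved in leaf tissue. Of 14 MADS-box genes, chosen after the values were seen, only 8 could be tested, and of these 5 were higher and 2 lower in white than in green sectors. PI (at least 156-fold), CAL (at least 5.25-fold), SEP3 (log2 +2.01), FUL (+1.97) and SEP4 (+0.89) rose, and SEP1 (at least 26.3-fold) and AGL24 (log2 −2.68) fell. The same 7 genes changed the same way against wild type, where SEP3 rose by 3.77 and FUL by 3.03. In green sectors against wild type SEP3 (log2 +1.76) rose and PI fell at least 3.65-fold. UPL2, also chosen after its values were seen, stood at −5.18 in wild-type replicate 3 and between −0.22 and 0.44 on the other 8 arrays.

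Every test of the 3 patterns below was chosen only after the pattern was seen, while the exchange of array labels was planned. Of the 10 ways to split the 6 arrays of a comparison, only the real split (1 of 10) reached the real count in each. White against green sectors gave 8136 genes and at most 0 in another split, white sectors against wild type 7832 and at most 0, and green sectors against wild type 124 and at most 68. With 10 splits a share under 0.05 cannot be reached. White and green sectors with the same number share a slide and may be paired, and 4 of their splits, the real one included, part all 3 such pairs. The other 3 gave 0 genes, and with the replicate number as a block 0 against 9054 for the real split, but with 4 splits a share under 0.25 cannot be reached. The remaining splits keep a pair together on each side and also gave 0. The split with 68 set wild-type replicates 2 and 3 and green replicate 2, the arrays of slide 2, against the rest, and with the slide as a block 55 genes were called.

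Wild-type replicate 3 differed from the other wild-type arrays, and its leaves may have been collected at another phase of the day. Evening-phased clock genes deviated from day-phased ones by a median of 2.00 log2 units on that array, with all 6 evening genes higher and all 6 day genes lower (two-sided exact permutation p = 0.013, over genes). That p is the lowest this test can give, and clock genes on a single array are not independent, so it does not establish a difference in phase. The same exact p was reached at 0.54 on green replicate 2, and at −1.30 and −0.91 on wild-type replicates 1 and 2, whose deviations are partly measured against replicate 3. The slide alone does not account for the difference, since replicates 2 and 3, on the same slide, correlated at 0.960 across genes against 0.982 for replicates 1 and 2 on different slides, but deviations of replicate 3 followed those of green and white replicate 2 on that slide (correlations of 0.571 and 0.302), so a part from the slide remains open. An exchange with a green sector array predicts a low VAR2, but VAR2 lay 2.72 above the highest green array there, against 2.73 for the lower of the other wild-type arrays, and with no time of collection in the labels a difference in age or handling remains open.

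Plastid-encoded transcripts were higher in green sectors than in wild type as a group only at camera's preset correlation (adjusted p = 0.342 with an estimated one, and 1 of 66 called over all genes), and a shift could come from the mutant's plastids or from how organelle RNA entered the labelling. A single wild-type array did not account for it: the median was 0.43 or more with any of them left out. Scaling between arrays did not either, with a median of 0.51 or more under the other scalings. Mitochondrial-genome transcripts were also higher, with a median of 0.45 and 11 of 54 called higher in green sectors, and a median of 0.81 in white sectors against wild type. In green sectors camera's unadjusted p with an estimated correlation was 9.3e-04 for them and 0.0342 for plastid-encoded transcripts. Nuclear loci in a region that copies mitochondrial DNA had a median of 0.43 there, with 13 of 64 called higher. Higher transcripts of both organelles could come from a difference in how far their RNA was primed by oligo-dT. A rise of both organelles' RNA in the mutant is as compatible with these values.

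Vein, guard cell and cell cycle genes were lower in white sectors, as groups at camera's preset correlation but not at an estimated one, which might reflect the slides, a smaller share of veins or less young dividing tissue. Slides did not account for it, since the highest median of the 4 groups within any slide was −1.08. Xylem markers fell further than phloem markers by 1.29 log2 units (−1.29, two-sided exact permutation p = 0.00591, over genes, which are not independent). A lower share of vein tissue alone would move both alike only if both were confined to veins in fixed proportions, which was not tested. A lower share of dividing tissue alone would lower cytosolic ribosomal protein genes if these followed division alone, and they were higher by 0.78. These values therefore do not exclude a smaller share of either tissue. A mixture of such changes, or regulation within each cell type, was not tested.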
